A study of Mus musculus with 48 samples.

How the data were processed

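RNA was sequenced from 48 single mouse fetal liver cells of 1 group, BFU-E. Per the labels, cDNA was made on a Fluidigm C1 chip with SMART-Seq chemistry, libraries with Nextera XT, and 96 libraries were pooled. Reads were aligned to mm10 with TopHat2 2.0.12 and counted per gene with featureCounts 1.4.6 of Subread, as the authors state. The deposited table of raw counts holds whole-number counts for 24062 genes, of which 9946 had no read in any cell. The deposited table of log2 normalized counts was checked against the counts and equals log2 of the count divided by a DESeq median-of-ratios size factor, plus 1, within a tolerance of 1e-06. The table columns are run codes that match no sample title, so cells carry no label beyond the group and are treated as 1 sample. Intervals and limits from a count of 0 cover counting error only, because reads without molecular identifiers are not independent molecules.

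Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1. Figures were drawn with matplotlib 3.10.9. Cells needed 100000 counts and 1500 genes. CPM used TMM library sizes, with factors from 0.419 to 1.70, and log2 values a pseudocount of 1. Genes tested one by one across the table needed a read in at least 10 cells and a mean of 5 CPM, which 8601 did. Gene positions are from GENCODE for GRCm38.

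Lists were fixed before the data were examined: erythroid regulators, erythroid maturation, stem and early progenitor, TGF-beta pathway, glucocorticoid response, cyclin-dependent kinase inhibitors, S phase, G2/M phase, immediate early and stress, glycolysis and hypoxia, and cytokine receptors, and as markers of other cell types megakaryocyte, mast cell and basophil, neutrophil and monocyte, macrophage, lymphoid, hepatoblast, and endothelial and stromal. Ahsp, Epb41, Epb42, Pkm2, Trfr2, Ly6g, Ly76 and Adgre1 are not in the table. Named genes were taken from the TGF-beta receptors, the genes of the sort, list members beside their list's count, the 15 genes farthest above the variability trend and the 12 genes of smallest p in each direction of each edgeR association. Genes singled out in the closing section were chosen after their values were seen.

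Variability was the squared coefficient of variation of CPM over a lowess trend on the mean, with a ratio of 2 as threshold. Lists were compared with 10000 random lists of the same size, matched on mean expression in 20 bins. The 2-set structure used k-means with 20 starts on 10 components of the 500 most variable genes, and 10000 Gaussian draws. Each draw had fewer starts than the cells, which can raise its ratio and make p too small. Correlations used 100000 two-sided permutations and Benjamini-Hochberg adjustment, and a threshold of 0.05. The smallest p that these permutations can give is 1e-05. The planned correlations used all 48 cells. After the structure test they were reported in the 46 cells of the larger set, as were the tests of genes read together in a cell, the rank tests across all genes and the comparisons across the gap in Tgfbr3. Detection, variability, list co-variation, structure and edgeR results kept all 48 cells unless stated. Associations across all genes used quasi-likelihood tests of edgeR with 1 continuous covariate.

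Tgfbr3 levels proved to have a gap in the 46 cells. Cells above and below the widest gap on the log2 scale were then compared by a permutation test on ranks, and correlations with Tgfbr3 were made within each side. A limit of 10 CPM, which moves 1 cell to the lower side, was tried first. Both were chosen after seeing the data, and the comparison of marker scores was too.

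Alternatives were other normalizations, filters, pseudocounts and thresholds, thinning of every cell to 246007 counts, leaving out the 5 cells of lowest total count or the cell with Xist and Y-linked reads, the authors' log2 table, the number of genes detected as covariate, DESeq2, limma and rank tests. The steps were tested on simulated data. EdgeR recovered 0 of 50 genes with a slope of 0.1, 0 of 50 at 0.2, 15 of 50 at 0.4 and 10 of 50 at −0.4, with 4 calls among 8400 genes without a slope. The simulated counts were negative binomial and independent between genes. With the real counts, random orders of the covariates called medians of 171 and 140 genes, so the simulation understates false calls. The correlation step recovered 31 of 34 genes tied to an axis at an r of 0.65, with 2 false calls. The variability step recovered 153 of 200 genes, with 416 false calls. The structure test found 2 cells displaced by 8 SD in 15% of 60 draws and a single cloud split in 0%.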

Results

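The data are RNA sequencing counts from 48 single cells of mouse fetal liver, all labelled BFU-E, the early erythroid burst-forming progenitor. The labels describe a sort at embryonic day 14.5 for cells without lineage markers, with c-Kit, and with the 10% lowest CD71. The growth protocol also sorts BFU-E on the type III TGF-beta receptor. Full-length cDNA was made in a microfluidic chip and sequenced without molecular identifiers. The columns of the count table could not be matched to sample titles, and the labels name no animal, litter, chip or batch. The 48 cells therefore count as 1 sample, no labelled groups are compared, and every p-value speaks only of the spread between these cells. Sets of cells compared below were made from the cells' own transcript levels, and their cells are not replicates of a condition. Total counts ran from 246007 to 3211186 per cell, with a mean of 1937297 ± 674844 (SD, n = 48). Each cell had reads of 5180 to 7935 genes, with a mean of 6772 ± 667 (SD, n = 48). All 48 cells passed the minimums of 100000 counts and 1500 genes.

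The first question was whether the cells carried the transcripts of the sort. Kit, the receptor for stem cell factor, had a read in 46 of 48 cells (95% Clopper-Pearson interval 85.7 to 99.5%), at a mean of 422 ± 681 CPM, which are counts scaled to a common library size (SD, n = 48). Tfrc, which encodes CD71, had a read in 44 cells (interval 80.0 to 97.7%), at 249 ± 412 CPM. Transcripts of several surface markers that the sort excluded were also read. Cd34 was read in 36 cells, Fcgr3, which encodes CD16, in 39 and Ptprc, which encodes CD45 and its B220 form, in 43, and they reached 10 CPM in 19, 20 and 26 cells. Itgam was read in 14 cells, Ly6a in 7 and Cd3e in 1. Counts per gene do not tell the B220 form of Ptprc from other forms of CD45. A transcript read does not measure the surface protein on which the sort acted.

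Receptors of TGF-beta were next, since the series concerns TGF-beta inhibitors and the growth protocol sorts BFU-E on the type III receptor. Tgfbr3, the type III receptor (GRCm38 chromosome 5, 107106570 to 107289629, minus strand), had a read in 36 of 48 cells (interval 60.4 to 86.4%), at 167 ± 381 CPM (SD, n = 48). It reached 10 CPM in 24 cells and 100 CPM in 15, with a highest value of 2335 CPM. Tgfbr1 had a read in 26 cells (interval 39.2 to 68.6%), at 37.6 ± 128 CPM. That mean rests on few cells: the 2 cells called macrophage-like below held 599 and 76.3 CPM, and 1 other cell 646 CPM. Tgfbr2 had a read in 10 cells (interval 10.5 to 35%), at 6.89 ± 29.9 CPM. Most of the cells with a read of Tgfbr1, and most of those with a read of Tgfbr2, were below 10 CPM. Of the 32 genes of the TGF-beta pathway list, 19 had a read in at least 10 cells.

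**Figure D1:**
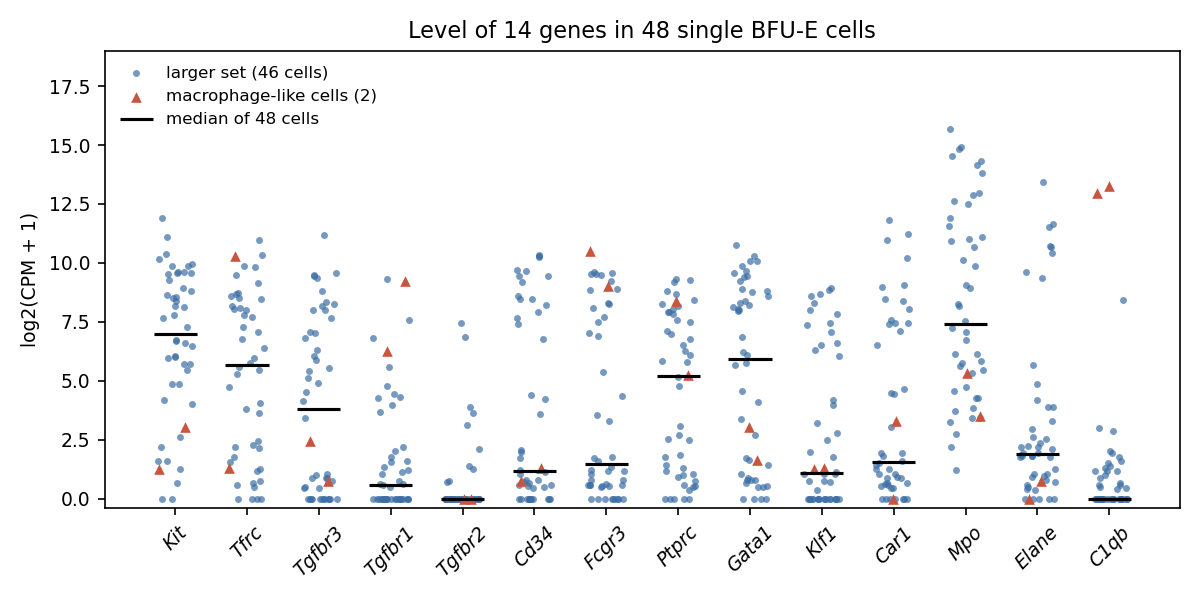
Level of 14 genes, as log2(CPM + 1), in each of the 48 cells, with a black bar at the median of the 48 cells and triangles for the 2 macrophage-like cells. Mpo runs from 1.32 to 53282 CPM, and Tgfbr3 from 0 to 2335 CPM.

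Erythroid regulators were read in many cells, often at a low level. Gata1, the erythroid master regulator (GRCm38 chromosome X, 7959260 to 7978071, minus strand), had a read in 44 of 48 cells at 287 ± 404 CPM (SD, n = 48), and reached 10 CPM in 28. Klf1, an activator of globin genes, had a read in 31 cells at 71.0 ± 134 CPM and reached 10 CPM in 16, and Epor had a read in 21 cells and reached 10 CPM in 10. Of 18 erythroid regulators, 16 had a read in at least 10 cells. Of the 36 erythroid maturation genes in the table, 24 did so. Car2, a carbonic anhydrase, and Prdx2, a peroxiredoxin, were read in all 48 cells, at 692 ± 817 and 665 ± 503 CPM. Hba-a1, Hba-a2, Hbb-b1, Hbb-b2, Hbb-bs and Hbb-bt were listed at 0 in all 48 cells. The labels do not say whether globin reads were removed before deposit, so these values set no limit on globin expression. Alas2, the erythroid enzyme that starts heme synthesis, was read in 2 cells, and Slc4a1 and Sptb in 0 of 48, which allows a share of cells with a read of up to 6.25% by the limit of 3 counts, and of up to 7.40% by the Clopper-Pearson interval.

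Other states were read as well. All 42 S phase genes and all 52 G2/M phase genes had a read in at least 10 cells, and Mki67 and Top2a were read in all 48 cells, at 621 and 497 CPM. Mpo, the myeloperoxidase of neutrophil precursors (GRCm38 chromosome 11, 87793581 to 87804413, plus strand), was read in all 48 cells at 4940 ± 10549 CPM (SD, n = 48). Its median was 169 CPM, and 18 cells reached 1000 CPM. Of the stem and early progenitor list, 23 of 28 genes had a read in at least 10 cells, against 15 of 20 immediate early and stress genes and 18 of 20 glycolysis and hypoxia genes in the table. The counts were 17 of 19 for cytokine receptors, 9 of 12 for glucocorticoid response and 5 of 10 for cyclin-dependent kinase inhibitors.

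The series asks for subpopulations of BFU-E, so spread between cells was examined. The squared coefficient of variation was at least 2 times its trend in 1386 of 8601 genes. The 15 genes farthest above the trend were Ctsb, Ftl1, Ctsd, Hmox1, Mpo, Slc40a1, Sepp1, Lgmn, Actb, Slc35f6, C1qb, Marcks, Fth1, Cd5l and Ctss, from 83.6 down to 18.2 times the trend. The highest cell was 1 of the same 2 cells for 14 of them, all but Mpo. In the other 46 cells 1189 genes passed, with Mpo in the first place at 46.9 times the trend and Elane, a neutrophil protease, at 17.8 times. No p-value belongs to these counts, since the labels name no spike-ins that would measure technical spread.

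A split into 2 sets by k-means separated those 2 cells from the other 46. The ratio of within-set to total sum of squares was 0.682, against a median of 0.762 in draws from 1 Gaussian cloud (p = 0.0150, one-sided, 10000 draws). This p may be too small, since the draws had fewer k-means starts than the cells. Genes with the highest fold of the mean over the 2 cells were Mpeg1, Lgmn, Vsig4, Fcna, Dse, Timd4, Il1a, Kcnj10, C1qa and Ctsh. Vsig4 and Kcnj10 rest on 1 of the 2 cells, since the other had 0 and 2.77 CPM. The 10 genes include the macrophage markers Timd4 and C1qa, high in both, and the 2 cells are called macrophage-like. C1qb, a complement component, averaged 8889 CPM in them and 8.15 CPM in the 46, with 338 CPM in 1 of the 46 and at most 6.86 CPM in the rest. Hmox1, which breaks down heme, was at 17680 and 145 CPM in the 2 cells, at 474 CPM in that same 1 of the 46 and at most 2.71 CPM in the rest. Kit averaged 4.36 CPM and Gata1 4.70 CPM in the 2 cells. In the 46 cells alone the test did not call a split (ratio 0.859, p = 0.796). On simulated data it found a clear split of 18 and 28 cells along the first component in 20% of 60 draws. It would therefore miss most such splits, and it cannot tell whether the 46 cells form 1 set or 2.

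**Figure D2:**
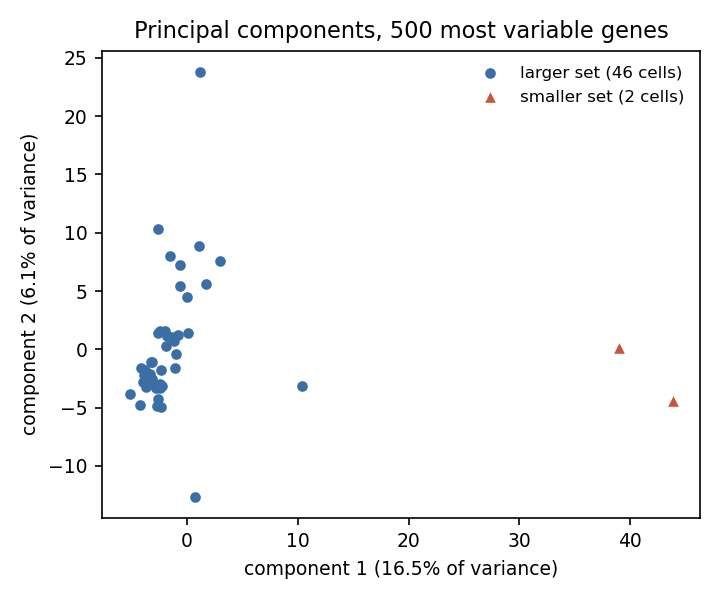
The first 2 principal components of the 500 most variable genes, with 16.5% and 6.12% of the variance, for the 46 cells of the larger set (circles) and the 2 macrophage-like cells (triangles). The 2 cells lie apart from the 46 on the first component.

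Gene lists differed in how far their members varied and moved together. The neutrophil and monocyte list and the macrophage list lay at percentile 100 of 10000 random lists matched on expression, followed by endothelial and stromal (99.97, 3 genes), cytokine receptors (99.3) and stem and early progenitor (98.6). Mean pairwise Spearman correlation lay among the highest 2.5% of random lists in 10 lists. It was 0.409 for neutrophil and monocyte, 0.359 for macrophage (0.215 over 7 genes in the 46 cells), 0.291 for megakaryocyte, 0.213 for erythroid maturation and 0.146 for erythroid regulators. It was 0.152 for G2/M phase, 0.139 for S phase, 0.107 for stem and early progenitor, 0.0761 for glycolysis and hypoxia and 0.0625 for immediate early and stress, the last at percentile 99.0 and at 96.0 in the 46 cells. The others had −0.00264 for the TGF-beta pathway (percentile 10), −0.0751 for cyclin-dependent kinase inhibitors (2.84, and 0.4 in the 46 cells, among the lowest 2.5% of random lists), 0.00944 for cytokine receptors (42.4), 0.0501 for glucocorticoid response (79.5) and 0.184 for endothelial and stromal (96.7). The mast cell and basophil, lymphoid and hepatoblast lists had 2 genes each and no value. Without the 5 cells of lowest total count, 3 lists passed for variability.

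Tgfbr3 levels had a gap. In the 46 cells, 25 had 9.75 CPM or more and 21 had 1.08 CPM or less, 12 of them no read. Since cells carry no label beyond the group, whether a sort on the type III receptor shaped the gap cannot be told. Across this gap Gata1 averaged 471 ± 450 CPM above and 94.0 ± 227 CPM below (SD, n = 25 and 21; adjusted p = 0.000468), and Car2 1136 ± 822 and 229 ± 488 CPM (0.000468). Cd34, a marker of early progenitors, went the other way, with 32.7 ± 120 and 416 ± 449 CPM (0.00260). At 10 CPM, 22 cells held Tgfbr3 and Gata1, 2 Tgfbr3 alone, 6 Gata1 alone and 16 neither (Fisher's exact test, adjusted p = 0.000164 over 16 tests). The gap was seen after the planned correlations had been made, and the comparisons of lists and list genes with Tgfbr3 are therefore given across it and within each side. A correlation or slope over all cells, edgeR's included, also holds this step.

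List scores, each the mean z-score over a list's genes, differed across the gap for 6 of 11 lists (two-sided permutation test on ranks, 100000 permutations, n = 25 and 21, Benjamini-Hochberg over 11). Erythroid maturation averaged 0.294 ± 0.454 above and −0.350 ± 0.327 below (p = 2e-05, adjusted p = 0.000110), and erythroid regulators 0.242 ± 0.307 and −0.288 ± 0.343 (2e-05, 0.000110). G2/M phase was higher above the gap (0.191 ± 0.305 and −0.228 ± 0.456, adjusted p = 0.00326). Stem and early progenitor (−0.138 ± 0.290 and 0.164 ± 0.396, 0.0193), immediate early and stress (−0.0739 ± 0.295 and 0.0879 ± 0.239, 0.0193) and glycolysis and hypoxia (−0.121 ± 0.359 and 0.144 ± 0.316, 0.0360) were lower. The TGF-beta pathway (0.241), S phase (0.281), glucocorticoid response (0.281), cytokine receptors (0.281) and cyclin-dependent kinase inhibitors (0.358) did not pass. Without the 5 cells of lowest total count, stem and early progenitor and glycolysis and hypoxia no longer passed. Given the number of genes detected, immediate early and stress did not pass. That setting tested Pearson's r of residuals rather than ranks, so the change of test cannot be told apart from the covariate.

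Within each side of the gap, no list score passed a test against the Tgfbr3 level. Among the 25 cells above it, erythroid regulators had a Pearson r of −0.281 (permutation p = 0.175, adjusted p = 0.377) and a Spearman rho of −0.29 (p = 0.155, adjusted p = 0.322), and erythroid maturation an r of −0.120 (p = 0.568, adjusted p = 0.781) and a rho of −0.12 (p = 0.577, adjusted p = 0.778). Among the 21 cells below, erythroid regulators had an r of 0.457 (p = 0.0380, adjusted p = 0.209) and a rho of 0.42 (p = 0.0593, adjusted p = 0.326). Neither side had any of the 11 lists, the 7 marker lists or the 234 list genes past an adjusted p of 0.05 by rank. With the limit at 10 CPM, erythroid regulators passed by Pearson's r in the 22 cells below it (r 0.588, adjusted p = 0.0283) and not by rank (rho 0.50, adjusted p = 0.202). These 22 cells are the 21 below the gap and the cell at 9.75 CPM. The planned rank correlations over all 48 cells had called 6 of 11 lists and 40 of 235 list genes, and those over the 46 cells 5 of 11 and 40 of 234. These calls mix the step between both sides with any relation inside them. With 25 and 21 cells, weak relations within a side were not detectable. The 21 cells below the gap had 0 to 1.08 CPM of Tgfbr3, 12 of them no read. A level so near the floor is mostly counting error, so the tests below the gap could not show a relation.

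**Figure D3:**
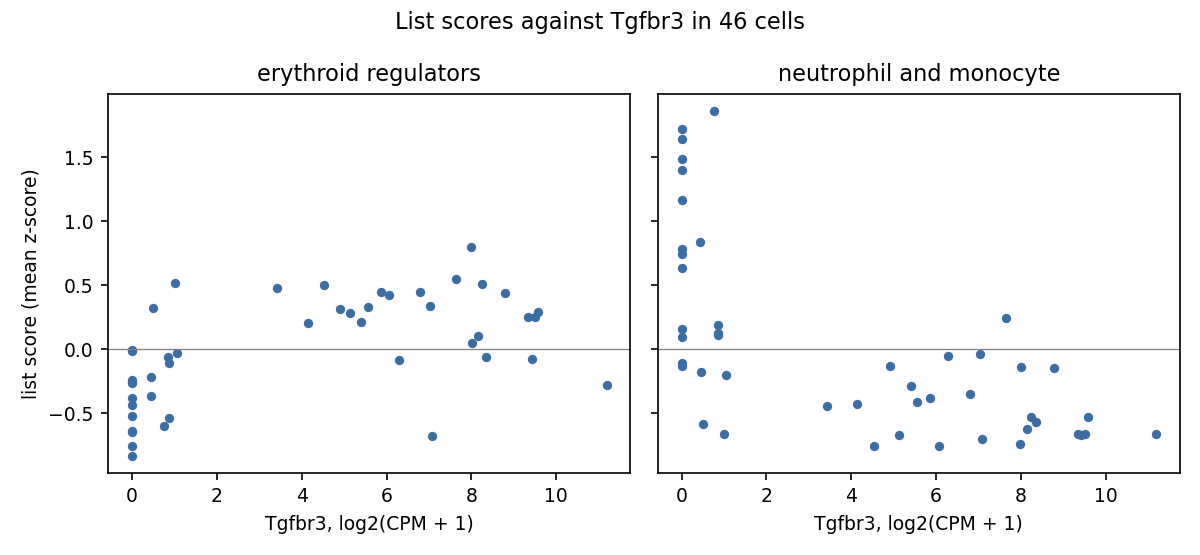
List scores of the erythroid regulators (left) and of the neutrophil and monocyte markers (right), as mean z-scores, against Tgfbr3 as log2(CPM + 1) in 46 cells, 1 point per cell. The 25 cells above the gap in Tgfbr3 average 0.242 and −0.444, and the 21 cells below it −0.288 and 0.528.

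By gene, 38 of 234 list genes differed across the gap, 22 higher above it and 16 lower (permutation test on ranks, n = 25 and 21). Of 16 erythroid regulators 5 were higher, among them Gata1, Gfi1b (278 ± 306 and 45.3 ± 148 CPM) and Klf1 (104 ± 142 and 38.4 ± 123 CPM), and adjusted over the list alone 6. Of 24 erythroid maturation genes 8 were higher, among them Car2, the heme-pathway enzyme Cpox (62.0 ± 108 and 9.50 ± 24.4 CPM) and Blvrb (217 ± 206 and 22.1 ± 69.7 CPM), and adjusted over the list alone 13. Of 52 G2/M phase genes 7 were higher, among them Hmmr and Aurkb, and adjusted over the list alone also 7. Of 23 stem and early progenitor genes 6 were lower and 0 higher, among the lower Cd34, Hlf and Runx1, and adjusted over the list alone 6 were lower and 1 higher. Of 18 glycolysis and hypoxia genes 1 was higher (Hk1) and 4 lower (Pgam1, Hk2, Gpi1 and Gapdh, the last at 926 ± 299 and 1324 ± 358 CPM), with the same counts adjusted over the list alone. Of 17 cytokine receptors 1 was higher (Epor) and 3 lower (Cxcr4, Csf2rb and Notch1), again with the same counts adjusted over the list alone. In the TGF-beta pathway list Ltbp1, a latent TGF-beta binding protein, was the 1 of 18 genes that was higher, also adjusted over the list alone. Cdkn1a was lower among 5 cyclin-dependent kinase inhibitors, also adjusted over the list alone, and Gins2 among 42 S phase genes, with 0 adjusted over the list alone. Glucocorticoid response had 1 of 8 lower, Cebpb, and adjusted over the list alone 1 lower and 1 higher. Immediate early and stress had 0 of 15, also adjusted over the list alone.

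Markers of other cell types were set against Tgfbr3 in the same way, a comparison added after the levels had been seen. Mpo averaged 133 ± 219 CPM in the 25 cells above the gap and 11131 ± 13782 CPM in the 21 below (adjusted p = 0.000173 over 52 genes), and Prtn3, another neutrophil protease, 16.6 ± 35.6 and 723 ± 839 CPM (0.000173). Of 12 neutrophil and monocyte genes, 8 were lower above the gap, and adjusted over the list alone also 8. The score of that list averaged −0.444 ± 0.270 above and 0.528 ± 0.776 below (p = 1e-05, the smallest that the permutations can give; adjusted p = 7e-05 over 7 lists). Of 8 genes of the sort with a read in at least 10 cells, 5 were lower above the gap (Fcgr3, Ptprc, Cd34, Itgam and Fcgr2b) and Itga2b was higher, with the same counts adjusted over the list alone. Kit (522 ± 864 and 343 ± 398 CPM, adjusted p = 0.630) and Tfrc (306 ± 490 and 144 ± 205 CPM, 0.512) did not pass. Fcgr3 averaged 20.8 ± 71.0 and 303 ± 307 CPM (0.000173), and Ptprc 58.3 ± 150 and 205 ± 179 CPM (0.000260), the latter without regard to its B220 form. Elane and Gata1 reached 10 CPM together in 2 of 46 cells, Gata1 alone in 26, Elane alone in 11 and neither in 7 (Fisher's exact test, adjusted p = 0.000987). Mpo did not separate so at that limit. Gata1 and Mpo reached 10 CPM together in 22 of 46 cells (same test, adjusted p = 0.0835), and Tgfbr3 and Mpo in 19 (0.217). At 100 CPM these pairs were together in 8 (0.0113) and 3 cells (0.00182).

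Other marker scores were also unequal across the gap. The megakaryocyte score averaged 0.211 ± 0.673 above and −0.251 ± 0.242 below (adjusted p = 0.0262), with 3 of 9 genes higher (Vwf, Itga2b and Gp5), and adjusted over the list alone also 3. The mast cell and basophil score (2 genes, −0.362 ± 0.611 and 0.431 ± 0.817, adjusted p = 0.00210), the hepatoblast score (−0.202 ± 0.379 and 0.241 ± 0.593, 0.00737) and the lymphoid score (−0.191 ± 0.443 and 0.228 ± 0.558, 0.0146) were lower. By gene the counts lower were 1 of 2 for mast cell and basophil, 0 of 5 for hepatoblast and 2 of 4 for lymphoid, each the same adjusted over the list alone. Hepatoblast genes Apoa1 (0.0745 and 0.402 CPM), Serpina1a (0.638 and 1.60) and Dlk1 (0.484 and 1.74) were near the floor, while Trf and Krt18 were higher. Lymphoid genes Cd3d (0.919 and 2.01 CPM) and Lck (3.78 and 0.647) were also low, while Cd79b and Nkg7, the 2 that passed, were higher. The macrophage score (adjusted p = 0.418, 0 of 11 genes) and the endothelial and stromal score (0.784, 1 of 3 genes higher, Col1a2) did not pass, with the same gene counts adjusted over the list alone. Without the 5 cells of lowest total count 2 of the 7 scores passed, those of neutrophil and monocyte and of mast cell and basophil.

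**Figure D4:**
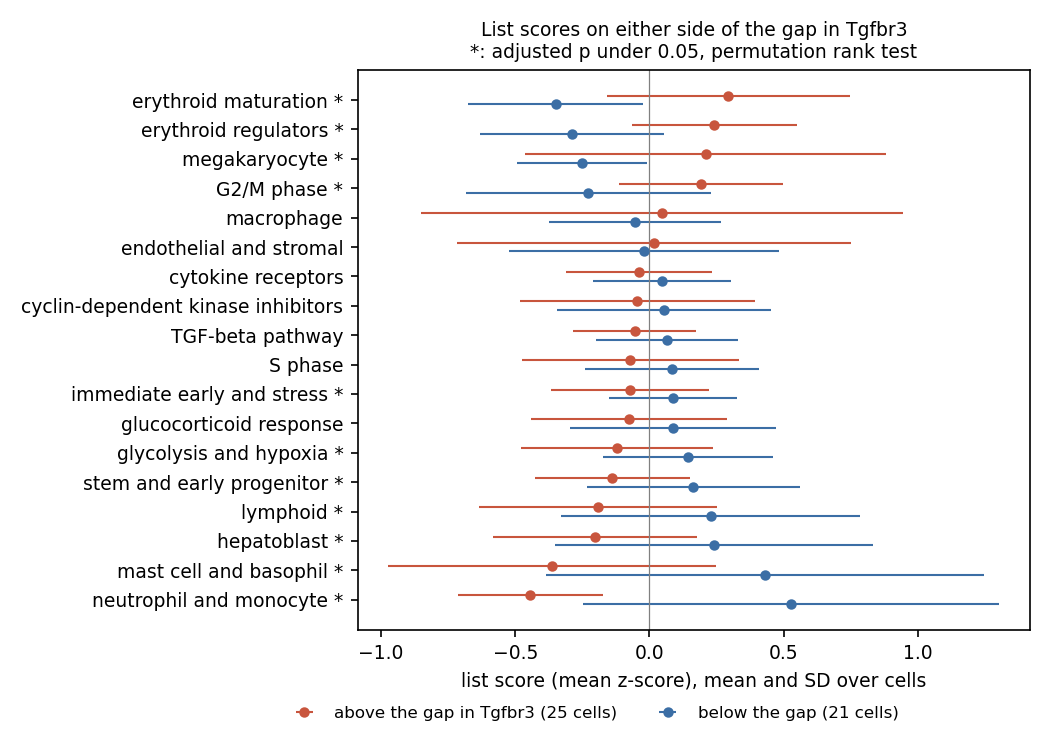
Mean and SD over cells of the scores of 11 lists and 7 marker lists, in the 25 cells above the gap in Tgfbr3 and the 21 cells below it, with a star at lists past an adjusted p of 0.05. Neutrophil and monocyte markers lie lowest and erythroid maturation highest in the cells above the gap.

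Across all genes, edgeR with the log2 Tgfbr3 level as covariate called 517 of 8600 genes in the 48 cells, 164 positive and 353 negative. DESeq2 gave the opposite balance, with 646 positive and 462 negative. Negative genes were led by Rab31 (log2 slope per log2 unit of Tgfbr3 −1.25 ± 0.14 SE, adjusted p = 4.27e-08), BC035044 (−1.22), Emb (−1.08), Anxa3 (−1.26), Pstpip1 (−1.30) and Mpo (−0.80 ± 0.11, adjusted p = 8.19e-07). Aoah, Tfec, Ctsg, Clec12a and B4galnt1 were also among the 12 of smallest p, and Ctsg encodes a further neutrophil protease. Positive genes were led by Sepsecs (0.94 ± 0.14, adjusted p = 6.11e-06), Prkg1 (0.82), Zfp90 (1.06), 1110028F11Rik (0.91), Slamf1 (1.20) and Ticam1, then Col1a2, Fam122b, Trib2, Optn, Pcgf2 and Pomt2, each read in 10 to 24 cells. Since random orders also gave calls, the adjusted p of single genes in edgeR is too small here, and that of Sepsecs by rank was 0.363. A rank test in 46 cells called 162 of 8481 genes, 45 positive and 117 negative, and 101 of them were also called by edgeR with the same sign. It called 12 of the 12 negative genes of smallest p in edgeR and 4 of the 12 positive ones (Prkg1, 1110028F11Rik, Trib2 and Optn). Random orders of the Tgfbr3 level over the cells called a median of 171 genes, with up to 148 positive and 173 negative. Within the sides of the gap the rank test called 0 genes, with 461 and 531 at an unadjusted p under 0.05 where 424.1 would fall by chance. Below the gap the Tgfbr3 level is too near the floor for a relation to show.

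The second covariate was the erythroid maturation score, along the direction of differentiation. EdgeR called 525 of 8577 genes, 120 positive and 405 negative. Positive genes were led by Ces2g (log2 slope per unit of score 7.21 ± 0.78 SE, adjusted p = 7.58e-09), Nxpe2 (7.23), Nqo1, Rps6ka6, Pklr, the pyruvate kinase of red cells (7.82), and Slc26a1, then Evc2, Atp1b2 (8.50), Tspan8, Cmpk2, Slc38a5 and Sh2d4a. Negative genes were led by Vsig4 (−10.85 ± 1.39, adjusted p = 8.39e-07), Itpripl2, Lgals3bp, Ptpro and Mpeg1, and Tmsb4x, Il6ra, Nedd9, Mpo (−5.77), Cebpa and Lbp were also among the 12 of smallest p. Vsig4 and Mpeg1 are among the genes of highest mean fold in the 2 macrophage-like cells. In the 46 cells edgeR called 434 genes, 118 positive and 316 negative, 398 of them shared. The rank test called 222 of 8458 genes, 117 positive and 105 negative, with 6 of the 12 positive genes of smallest p in edgeR among them. Of the 12 negative ones 5 were called, and Vsig4, Itpripl2, Ptpro, Mpeg1 and Il6ra were not tested, since they missed the filter in the 46 cells. Random orders of the score called a median of 140 genes, with up to 141 positive and 210 negative, so the 120 positive calls lie within what random orders gave and the 405 negative ones beyond it. Limma called 227, 135 positive and 92 negative.

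Between list scores, 4 of 55 pairs passed by rank over the 46 cells (permutation p, Benjamini-Hochberg over 55), against 6 in the planned test over all 48 cells and 8 with the authors' log2 table, a pseudocount of 0.1, the mean of ranks or thinned cells. The 6 add erythroid regulators with cyclin-dependent kinase inhibitors (rho −0.40) and with immediate early and stress (rho −0.40), both at an adjusted p of 0.0463. Erythroid maturation rose with erythroid regulators, with a Spearman rho of 0.80 (p = 1e-05, adjusted p = 0.000550) and a Pearson r of 0.766 (p = 1e-05, adjusted p = 0.000550), and r was 0.747 without the 2 farthest cells. It fell as stem and early progenitor genes rose (rho −0.57, p = 5e-05, adjusted p = 0.00137; r −0.586, p = 6e-05, adjusted p = 0.00165; r −0.594 without the 2 farthest cells). S phase rose with glycolysis and hypoxia (rho 0.53, p = 0.000280, adjusted p = 0.00513; r 0.531, p = 0.000180, adjusted p = 0.00330; r 0.469 without the 2). Erythroid maturation and G2/M phase passed by rank (rho 0.46, p = 0.00124, adjusted p = 0.0170) and not by Pearson's r (0.405, p = 0.00544, adjusted p = 0.0748; r 0.375 without the 2). That pair had an adjusted p of 0.0577 with a pseudocount of 10, 0.0813 without the 5 cells of lowest total count and 0.122 given the number of genes detected.

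Marker scores were also set against the erythroid regulators score over the 46 cells, a comparison added after the levels had been seen. Over all 48 cells, neutrophil and monocyte passed by rank and by Pearson's r (permutation, adjusted p = 7e-05 for each). There hepatoblast (0.00714) and mast cell and basophil (0.0269) passed by rank and lymphoid (0.0516) did not. By Pearson's r hepatoblast (0.0528), mast cell and basophil (0.0539) and lymphoid (0.0847) did not pass there. The hepatoblast and lymphoid scores rest in part on genes near the floor, as given above. The values that follow are for the 46 cells. Neutrophil and monocyte genes fell as erythroid regulators rose (rho −0.58, permutation p = 4e-05, adjusted p = 0.000280 over 7 lists; r −0.679, p = 1e-05, adjusted p = 7e-05; r −0.663 without the 2 farthest cells). Hepatoblast (rho −0.41, p = 0.00454, adjusted p = 0.0132; r −0.342, p = 0.0188, adjusted p = 0.0329; r −0.382 without the 2), lymphoid (rho −0.40, p = 0.00564, adjusted p = 0.0132; r −0.395, p = 0.00674, adjusted p = 0.0210; r −0.370 without the 2) and mast cell and basophil (rho −0.39, p = 0.00766, adjusted p = 0.0134; r −0.381, p = 0.00899, adjusted p = 0.0210; r −0.356 without the 2) also passed, and megakaryocyte, macrophage and endothelial and stromal did not (adjusted p by rank 0.698, 0.698 and 0.825).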

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

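The alternatives that use the 46 cells alone, both sides of the gap in Tgfbr3, 10 CPM of Tgfbr3, covariates of list scores or rank tests across all genes were chosen after the results were seen, as was every test of marker scores and of values across the gap. Each main value was paired with each of its alternatives. Settings chosen before the data were examined left 51 such pairs within 1.5 times the reported count or on the same side of the threshold and moved 20. Added settings left 44, moved 26 and took 1 below the threshold. For the other values, 947 planned and 425 added pairs were left, and 24 and 7 moved. Of these other pairs, 102 planned and 31 added ones fell below the threshold, and 11 and 12 rose past it. No value past its threshold turned to the other side under an alternative over all cells. Within the cells above the gap, rho with Tgfbr3 was below 0 and not past the threshold for erythroid regulators (−0.29), erythroid maturation (−0.12) and G2/M phase (−0.30), which are higher above the gap than below it. The balance of called genes turned: DESeq2 gave 646 positive and 462 negative genes for Tgfbr3 (edgeR 164 and 353), and limma 135 and 92 for the maturation score (edgeR 120 and 405). Where values moved, the cause was not tested unless the setting itself gives it.

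In the 46 cells the structure ratio was 0.859. At 5 CPM 3 cells held both Xist and Y-linked reads, and at 50 CPM 0. A ratio of 3 gave 605 variable genes and 1.5 gave 2361. Without the 5 cells of lowest total count, 3 lists passed for variability, 2 of 11 list scores correlated with Tgfbr3 and 2 of 7 marker scores differed across the gap. The count of list scores was 3 given the number of genes detected, 8 with the mean of ranks, and 0 given the neutrophil and monocyte score or the erythroid regulators score. List genes numbered 21 in thinned cells and 0 given either score. By rank, list scores, marker scores and list genes correlated with Tgfbr3 numbered 0 within the cells above and below the widest gap. They also numbered 0 within those above and below 10 CPM, and the rank test across all genes called 0 in each side of the gap. Below the gap the Tgfbr3 level is too near the floor for a relation to show. Marker scores correlated with Tgfbr3 numbered 5, against 3, with the authors' log2 table, without the cell holding Xist and Y-linked reads and without the cell holding C1qb and Gata1, which is the same cell. Pairs of lists numbered 7 with total counts and 8 with the authors' table, a pseudocount of 0.1, the mean of ranks or thinned cells, against 4.

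For Tgfbr3, DESeq2 called 1108 genes, no filter 2646, limma 140, the rank test 162, and edgeR 245 with the neutrophil and monocyte score as covariate and 209 with the erythroid regulators score. For the maturation score DESeq2 called 943, no filter 2478, limma 227 and the rank test 222. Depth limits the low range: 246007 counts in the shallowest cell leave a gene of 1 CPM mostly without a read there.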

Other observations

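All tests named here were chosen after the result was seen, except that of Mpo and its list taking a share of the counts.

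Sex-linked transcripts divided the cells. Xist, which silences the inactive X chromosome, reached 10 CPM without Y-linked genes in 25 of 48 cells, Y-linked genes without Xist in 20, both in 1 and neither in 2. Megakaryocyte genes were read in part, with 9 of 14 genes in at least 10 cells. Of markers of other types, 2 of 12 mast cell and basophil genes, 4 of 16 lymphoid, 5 of 15 hepatoblast and 3 of 15 endothelial and stromal genes had a read in at least 10 cells. Alb, the main product of hepatocytes, was read in 1 cell and Afp in 3. Hba-x, Hbb-y, Hbb-bh1 and Hbb-bh2, embryonic or fetal globin genes, were listed at 0 in all 48 cells.

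Genes called by edgeR numbered 517 against Tgfbr3 and 525 against the erythroid maturation score. Of 40 orders of each covariate over the cells, the real order included, 1 called as many genes in each case, the highest other orders calling 258 and 279. The full counts lay above all 39 random orders, which makes an order by chance unlikely as their source but does not exclude it. The 120 positive genes for the maturation score lay within them, since a random order called 141. That score is made from the same counts, so genes that move with its members are called against it. The 164 positive genes for Tgfbr3 stood against at most 148. With edgeR they numbered 177 with DESeq2 size factors, 175 given the number of genes detected and 159 in the 46 cells. They fell to 148 without the cell holding Xist and Y-linked reads, 133 without the 5 cells of lowest total count and 128 in 45 cells. Random orders were made over all 48 cells only, so chance is not excluded for them either. The negative counts of 353 and 405 stood against at most 173 and 210. No biological explanation was tested.

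Neutrophil and monocyte genes were low where Tgfbr3 was high, with a rank correlation of −0.70 over the 46 cells that holds the step across the gap. Given the number of genes detected it was −0.689 (adjusted p = 7e-05), and with the list left out of the library totals −0.70 (p = 1e-05), where the list took a median of 0.0433% and at most 6.62% of the counts, so the tables argue against both as the whole cause. A candidate explanation is a sort that holds granulocyte-monocyte progenitors beside erythroid ones. The sort excluded CD16/CD32 and CD34, yet transcripts of these markers were higher in the cells below the gap. Fcgr3 averaged 20.8 CPM above and 303 CPM below, Cd34 32.7 and 416 CPM, and Fcgr2b 0.365 and 92.5 CPM. Of 8 genes of the sort, 5 were lower above the gap and 1 was higher, Itga2b, at 18.9 CPM above and 0.317 CPM below. Transcripts do not measure the surface protein, so they do not tell whether the gate worked. Given the neutrophil and monocyte score, 0 of 11 list scores passed, with 2 at an unadjusted p under 0.05 (the closest was erythroid maturation, rho 0.33, p = 0.0275, adjusted p = 0.149). This cannot be told apart from progenitors of 1 kind that vary along an axis, because the score and Tgfbr3 share the same step and no second sort gate was sampled.

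A cell of the 46 held C1qb at 338 CPM and Hmox1 at 474 CPM beside Gata1 at 336 CPM, Car1 at 2009 CPM and Tgfbr3 at 199 CPM. Over 12 macrophage genes of at least 100 CPM in the 2 macrophage-like cells it had a median of 2.79% of their level (range 0.221 to 17.9%), against 0.0705% in the highest other cell, which argues against free macrophage RNA spread over the cells. It was the only cell with Xist (509 CPM) and Y-linked reads (12.9 CPM) at 10 CPM, with 0 others. Cells of 2 embryos in 1 chamber could give this, and carry-over was not tested. The median of 2.79% is low for a whole cell like the 2 macrophage-like ones, so these values do not show a macrophage in the chamber. The call of both Xist and Y-linked reads depends on the limit, since 3 cells held both at 5 CPM and 0 at 50 CPM. The total count of this cell ranked 23 and its 7803 genes detected ranked 4 of the 48 cells, and an engulfed cell stays open and was not tested.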
